A study of Homo sapiens with 8 samples.

How the data were processed

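U2 IP-seq libraries from K562 cells expressing Flag-tagged SF3B1, wild type or K700E, were analysed from the deposited tables of predicted branch points. Per the series design text, high molecular weight nuclear extracts were treated with nucleases, complexes were isolated with anti-SF3A2 or anti-Flag antibody, U2 snRNA fragments were degraded with an antisense oligonucleotide and RNase H, and libraries with inline barcodes were made with iCLIP reagents. Per the labels, inserts of 24 to 55 nt were kept after 11 to 14 PCR cycles, and PCR duplicates were removed by a degenerate sequence in the read. The extract text in the labels names HEK293 as the RNA source in a description of the read layout, while the other labels give K562. Libraries without antibody and of unselected extract were not analysed here.

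Per the submitters' processing notes, cutadapt, STAR 2.7.6a and hg19 were used. How clusters were found, how replicates were pooled and how branch points were predicted is not given in the sources used here. Each deposited table lists, per the file headers, a cluster, its chromosome, start and end, a branch point and the rank of that branch point. The rank is a score from 1 to 3 deposited by the authors, with ties, and what it was computed from is not given in the sources used here. Positions are printed as deposited, and whether they count from 0 or 1 is unknown. Cluster identifiers had the same coordinates in every table in which they occurred, and some carried a 3′ splice site mark, taken here as the authors' annotation. For SF3A2 K700E, 1 row had no cluster identifier and was left out. No column was left without a group.

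The 4 tables were compared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The planned analysis assumed values per site or sequence, and the tables hold positions and ranks, so the planned tests on counts, the branch nucleotide, the match to the U2 consensus, the distance to the 3′ splice site, the downstream sequence and U12-type sites were not run. In their place, the listing of clusters and the top-ranked branch point were compared. Branch points were shared if at the same nucleotide. A cluster was oriented by the end nearer to the mean of its top-ranked branch points over the tables. A switched cluster had 1 top-ranked branch point in both tables of 1 pair and another in both tables of the other pair, and the 3 ways of dividing the 4 tables into pairs were counted alike. The splits by immunoprecipitation and crossed served as the reference for disagreement between tables. Wilson intervals at the 95% level were used for shares, and normal or log-normal intervals for differences of means and odds ratios. They treat clusters as independent, which neighbouring clusters are not, and no p-value was computed because no group had replicate values.

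Regional shares used windows of 10 Mb with at least 60 Flag clusters listed for 1 genotype, bins of 1 Mb with at least 5, and intervals of 100 kb. No annotation of hg19 was used here, so no gene is named and the gene lists fixed before the data were examined gave no result. The rule for named sites took up to 12 sites per direction in order of chromosome and position among genes of those lists. It was applied without the gene condition, so all its sites lie on chromosome 1, and the few printed were picked from these. Regions, blocks and switch examples were chosen after their values were seen. The switch count was tested on simulated data with 20000 clusters, of which 200 were switched by 3 nt. It recovered 136 of them, with 171 clusters counted in the genotype split and 37 and 32 in the other splits. Errors were simulated independently in each table, which is not shown for the data, so the recovery and these counts need not carry over. The share toward the nearer end was 63.7% where 70.0% was simulated, and 96.6% of simulated clusters were oriented correctly. This missed a stricter limit set at first. Of the 687 misoriented clusters, 679 spanned under 25 nt, where a branch point simulated about 12 nt from 1 end is mostly no nearer that end than the other, so the limit was lowered to 95% and clusters of 30 to 38 nt were added as an alternative. Alternatives covered the overlap rule, ranks, cluster sets, orientation and windows.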

Results

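Branch sites bound by the U2 snRNP were mapped in K562 cells, an erythroleukemia line, engineered to express Flag-tagged SF3B1 with either the wild-type sequence or the K700E substitution. SF3B1 is the U2 snRNP subunit that clamps the duplex of U2 snRNA with the intron branch site, and K700E is a recurrent substitution in myeloid neoplasms. Complexes were isolated from nuclease-treated nuclear extracts with an antibody to SF3A2, another U2 snRNP subunit, or with an antibody to the Flag tag. There were 3 SF3A2 libraries per genotype and 1 Flag library per genotype, 8 libraries in all. Each of the 4 combinations of immunoprecipitation and genotype was represented by 1 table of read clusters, pooled over 3 libraries for SF3A2. Each cluster carried up to 3 ranked branch points on hg19. Because each combination had 1 table, no value has a replicate error. Bracketed ranges are 95% Wilson intervals over clusters or branch points and cover counting error only.

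The SF3A2 K700E table was the most extensive, with 253912 branch points in 116273 clusters. The SF3A2 wild-type table held 160905 branch points in 86103 clusters. The Flag tables were closer in size, with 134081 branch points in 73582 clusters for K700E and 124989 in 69448 clusters for wild type. Over the 4 tables there were 122826 distinct clusters, and 55666 of them (45.3%) were listed in all 4. The median cluster spanned 34 nt. The tables give positions and ranks without read numbers, so the depth behind each cluster is unknown.

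Clusters that the authors marked as lying at a 3′ splice site made up 60.9% of the SF3A2 K700E clusters (60.6 to 61.2%) and 61.0% of the SF3A2 wild-type clusters (60.6 to 61.3%). They made up 66.7% of the Flag K700E clusters (66.3 to 67.0%) and 67.7% of the Flag wild-type clusters (67.4 to 68.1%). Thus the Flag tables held a larger share of 3′ splice site clusters than the SF3A2 tables in both genotypes. Clusters listed in all 4 tables carried the mark in 69.7% of cases, against 57.6% for the 7217 clusters found in both K700E tables and neither wild-type table. Among the 460 clusters found in both wild-type tables and neither K700E table, 38.9% carried it (34.6 to 43.4%).

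The top-ranked branch point lay off the middle of its cluster, nearer 1 end. In clusters of 30 to 38 nt it was most often 12 or 21 nt from the cluster start, with a trough at 16 nt, in each of the 4 tables. Of the 122826 clusters, 60800 had their top-ranked branch points nearer the end and 61473 nearer the start in file coordinates. The tables carry no strand, so shifts are given relative to the nearer cluster end, with a median distance of 12 nt from the top-ranked branch point to that end in each table.

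**Figure D1:**
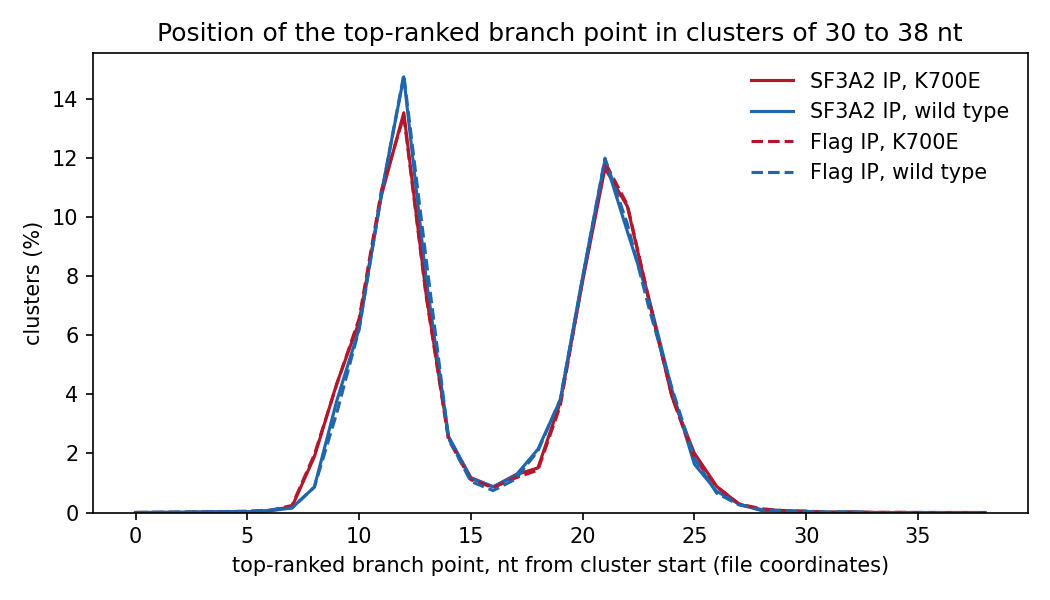
Percentage of clusters (y axis) by the distance in nt of the top-ranked branch point from the cluster start (x axis), for the 42702 clusters of 30 to 38 nt with 1 top-ranked branch point in each of the 4 tables; lines are the 4 tables. The curves have maxima at 12 and 21 nt and a trough at 16 nt.

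The first comparison asked which branch sites were listed for cells expressing mutant and wild-type SF3B1. The SF3A2 antibody does not select the tagged protein, so the SF3A2 tables compare cells rather than mutant and wild-type complexes. In the SF3A2 immunoprecipitation, 131022 branch points were listed at the same nucleotide for both genotypes, which was 81.4% of the wild-type branch points (81.2 to 81.6%) and 51.6% of the K700E branch points (51.4 to 51.8%). In the Flag immunoprecipitation 85951 were shared, 68.8% of the wild-type (68.5 to 69.0%) and 64.1% of the K700E branch points (63.8 to 64.4%). By cluster, 93.6% of the SF3A2 wild-type clusters and 84.2% of the Flag wild-type clusters were also listed for K700E. Relative to all branch points of both tables, the genotypes shared 46.2% in SF3A2 and 49.6% in Flag. The immunoprecipitations shared 45.2% within K700E and 52.6% within wild type. By branch point, the values between genotypes were within the range of those between immunoprecipitations of 1 genotype. By cluster, the genotypes shared 66.2% in SF3A2 and 69.1% in Flag, against 62.1% between immunoprecipitations in K700E and 68.8% in wild type, so the Flag value was above that range. Unequal table sizes cap such shares. Sizes differed most between immunoprecipitations within K700E (253910 against 134081 branch points) and least between genotypes in Flag (134081 against 124988). These values therefore do not show whether genotype or immunoprecipitation mattered more. The low share of SF3A2 K700E branch points found in wild type goes with the larger size of that table, which cannot be matched to the others by read depth.

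Most clusters specific to 1 genotype in SF3A2 were in neither Flag table, and those found in 1 Flag table were more often of the same genotype. Of the 35653 clusters listed for K700E but not for wild type in SF3A2, 22937 were in neither Flag table and 2642 in both. A further 7217 were found only for K700E in Flag and 2857 only for wild type, a K700E share of 71.6% (70.8 to 72.5%) among those in 1 Flag table. Of the 5483 clusters listed only for wild type in SF3A2, 4736 were in neither Flag table and 81 in both. The others gave 206 against 460, a K700E share of 30.9% (27.5 to 34.5%). Clusters present in both SF3A2 tables were split evenly, 7201 against 7184, or 50.1% (49.2 to 50.9%). The odds ratio between the first and the second class was 5.64 (4.76 to 6.69). It was 9.65 (6.90 to 13.5) in 3′ splice site clusters, 4.81 (3.92 to 5.90) in clusters without the mark and 15.2 in clusters of 30 to 38 nt. Without the 10 Mb windows that stood apart in both immunoprecipitations it was 4.87 (4.04 to 5.89).

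**Figure D2:**
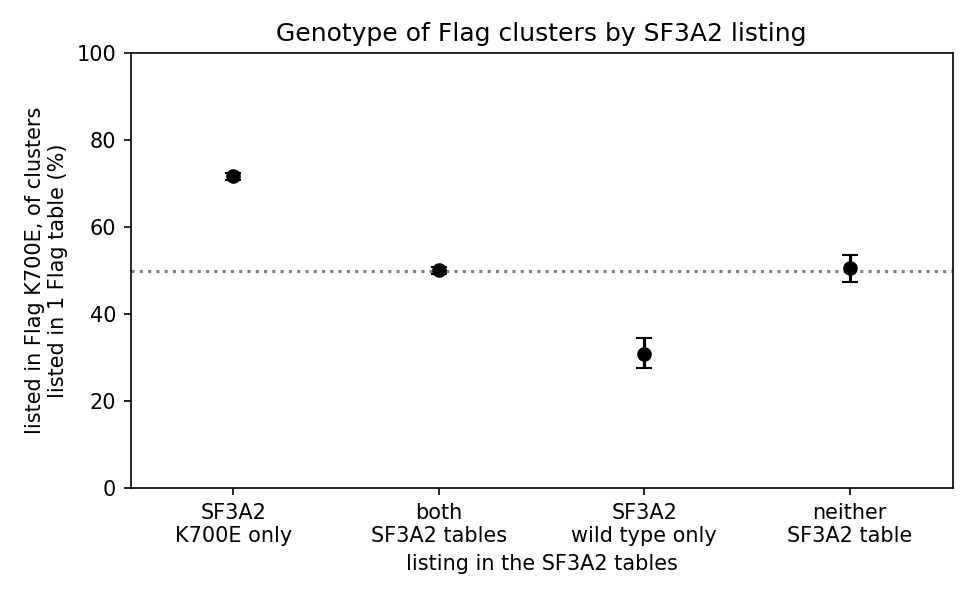
Percentage of clusters listed for K700E (y axis) among those listed in 1 of the 2 Flag tables, by their listing in the SF3A2 tables (x axis); points are shares and bars 95% Wilson intervals. The share was 71.6% for clusters listed only for K700E in SF3A2 and 30.9% for those listed only for wild type, around 50.1% for clusters of both.

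The first clusters along chromosome 1 found in both K700E tables and neither wild-type table included 898435 to 898471, with the top-ranked branch point at 898459 in both immunoprecipitations. At 983350 to 983385 and 1221264 to 1221299 the branch points were 983372 and 1221288. All 3 carried the 3′ splice site mark, as did 57.6% of this class. Other sites differed from these: the cluster at 891885 to 891922 carried no mark, with branch points at 891898 in SF3A2 and 891900 in Flag. In the other direction, chromosome 1 had a wild-type-specific cluster at 851076 to 851107, with the branch point at 851094. It also had 6 such clusters between 15627654 and 15700977, among them 15627654 to 15627686 with the branch point at 15627672 and 15692276 to 15692311 with the branch point at 15692297.

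Genotype-specific clusters occurred in many 100 kb intervals, and a few intervals held many of them. Of 12389 intervals with a cluster, 4092 held any of the 7217 clusters found in both K700E tables only and 388 any of the 460 found in both wild-type tables only. No chance expectation was computed for these intervals. On chromosome 12, the interval from 40.9 to 41 Mb held 47 clusters, of which 28 were found in both K700E tables only and 0 in all 4 tables. Intervals on chromosome 13 from 19.5 to 19.6 Mb and on chromosome 12 from 70.9 to 71 Mb held 18 and 17 K700E-specific clusters, again with 0 listed in all 4 tables. The interval with the most wild-type-specific clusters lay on chromosome X from 153.1 to 153.2 Mb, with 9 of 23 clusters. Intervals at 15.6 to 15.7 Mb of chromosome 1, 82.3 to 82.4 Mb of chromosome 9 and 73.7 to 73.8 Mb of chromosome 14 held 5 each. These intervals were named because they ranked highest, after their values were seen.

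Over wider regions, genotype-specific listing also varied along the chromosomes. Genome-wide, clusters listed for K700E only made up 86.7% of the genotype-specific clusters in SF3A2 and 57.9% in Flag. On the first 39 Mb of chromosome X these shares were 96.4% (94.1 to 97.8%) and 92.1% (88.1 to 94.8%, 233 against 20 clusters). From 40 to 60 Mb of the same chromosome they were 84.7% and 46.9% (39.7 to 54.2%, 83 against 94 clusters). On chromosome 17 the Flag share was 53.5% from 0 to 8 Mb, 17.1% from 8 to 20 Mb (11.9 to 24.1%), 81.9% from 20 to 47 Mb (78.7 to 84.7%) and 52.2% beyond 47 Mb. The SF3A2 shares over these 4 parts of chromosome 17 were 84.0%, 65.1%, 93.9% and 85.5%. The boundaries of these blocks were set after the values were seen.

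**Figure D3:**
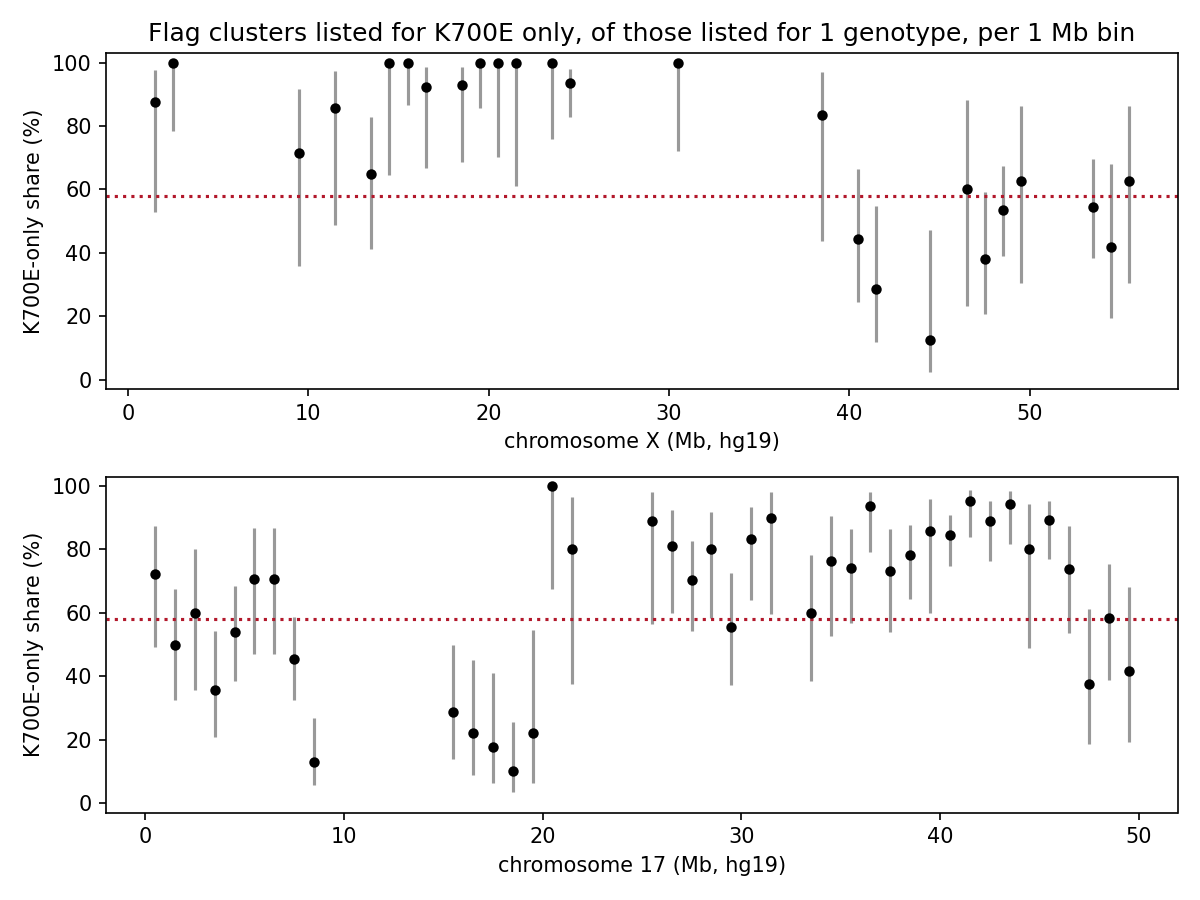
Percentage of Flag clusters listed for K700E only (y axis), among those listed for 1 genotype, in 1 Mb bins with at least 5 such clusters along chromosomes X (first 60 Mb) and 17 (first 50 Mb), position in Mb on the x axis; bars are 95% Wilson intervals and the dotted line is the genome-wide 57.9%. Bins below 39 Mb of chromosome X lie above the line, those from 8 to 20 Mb of chromosome 17 below it.

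Of 180 windows of 10 Mb with at least 60 genotype-specific Flag clusters, 20 lay above the genome-wide share in both immunoprecipitations and 19 below it in both, by their intervals, and 0 went opposite ways. If the immunoprecipitations were independent, 5.42 and 7.19 windows would lie above and below in both. Window shares in SF3A2 and Flag correlated with Pearson's r = 0.691 and Spearman's rho = 0.648 across windows, which are not replicates. Windows with high Flag shares included chromosome 11 from 120 to 130 Mb (81.2%) and from 110 to 120 Mb (80.0%), and chromosome 10 from 70 to 80 Mb (78.6%). Low shares were found on chromosome 22 from 10 to 20 Mb (25.7%), chromosome 18 from 10 to 20 Mb (28.6%) and chromosome 12 from 10 to 20 Mb (29.5%). By whole chromosome, the Flag share was highest on chromosome 21 at 72.7% (67.8 to 77.2%) and lowest on chromosome 18 at 46.7% (42.1 to 51.4%), chromosome Y left out.

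The next comparison asked whether the K700E and wild-type tables had different top-ranked branch points within the same cluster. Among 50765 clusters with a single top-ranked branch point in each table, 2615 (5.15%, 4.96 to 5.35%) had 1 top branch point in both K700E tables and another in both wild-type tables. Setting the SF3A2 tables against the Flag tables in the same way gave 660 clusters (1.30%), and the crossed arrangement gave 514 (1.01%). Of the oriented genotype switches, 1875 placed the K700E branch point closer to the nearer cluster end and 730 farther from it, or 72.0% closer (70.2 to 73.7%). The same share was 46.0% (42.2 to 49.8%) between immunoprecipitations and 49.4% (45.1 to 53.7%) in the crossed arrangement.

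**Figure D4:**
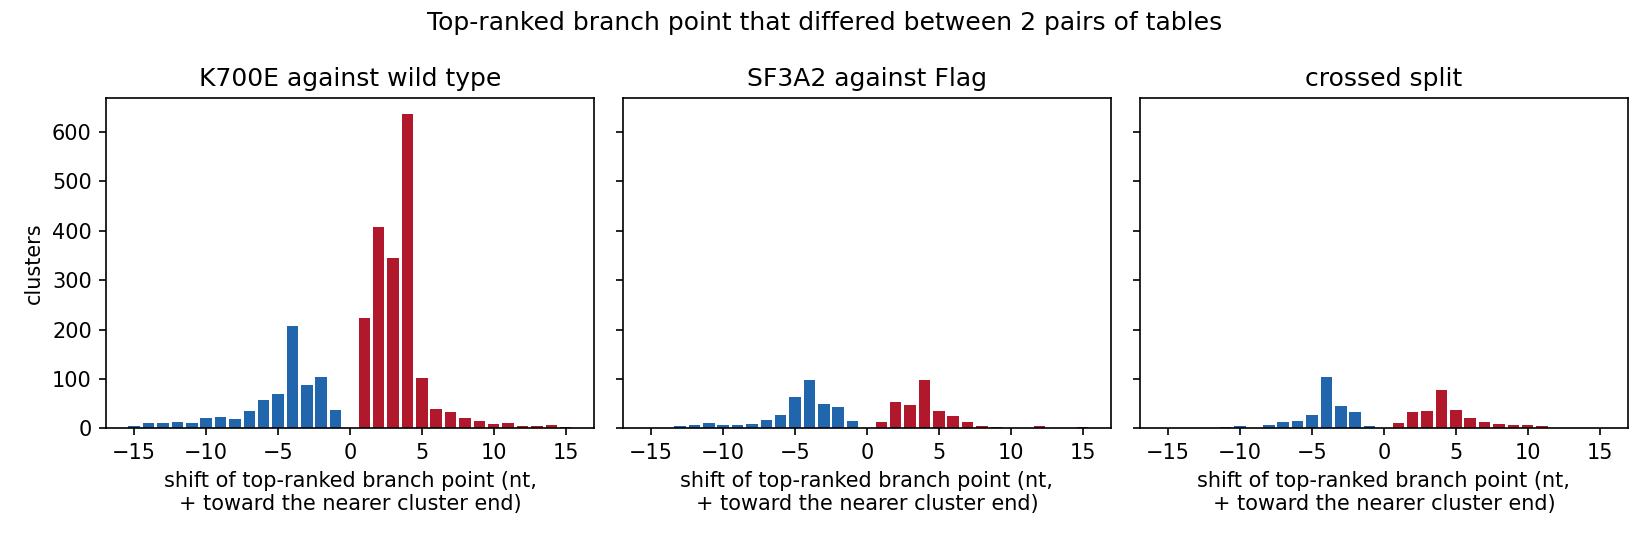
Number of clusters (y axis) by the shift in nt of the top-ranked branch point (x axis, positive toward the nearer cluster end, shown to 15 nt), for the 3 ways of dividing the 4 tables into pairs; red bars are shifts toward the nearer end and blue bars away from it. In the K700E against wild-type panel the tallest bar is 637 clusters at 4 nt toward the nearer end, against 208 at 4 nt away.

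In the genotype switches the excess of shifts toward the nearer end lay at short distances. From 1 to 4 nt, 1612 clusters shifted toward that end and 437 away, while beyond 4 nt there were 263 toward and 293 away. Room for longer shifts toward the end was limited. In clusters of 30 to 38 nt, the SF3A2 K700E branch point was most often 12 nt from the cluster start. It lay at 8 nt in 807 clusters and at 7 nt in 85. The lack of an excess beyond 4 nt is therefore not shown to be a trait of the genotype switches. A shift of exactly 4 nt was the most frequent, with 637 clusters toward the nearer end and 208 away. It was also the most frequent shift in each direction between immunoprecipitations and in the crossed arrangement. The distance of 4 nt was therefore not particular to the genotype switches. At this distance, only the genotype switches had more clusters toward the nearer end than away. Clusters with the 3′ splice site mark switched in 5.17% of cases and 72.6% of their oriented switches went toward the nearer end (70.5 to 74.6%). For other clusters the values were 5.11% and 70.5% (67.2 to 73.6%), so the intervals of the 2 kinds of cluster overlapped.

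On chromosome 1, the 3′ splice site cluster at 887526 to 887559 had its top-ranked branch point at 887535 in both K700E tables and at 887539 in both wild-type tables. At 7833461 to 7833499 the positions were 7833489 in K700E and 7833485 in wild type. At 11734888 to 11734922 they were 11734897 and 11734901. Each of these was 4 nt closer to the nearer cluster end in K700E, which is the start in file coordinates for the first and the third. Switches the other way included 1229585 to 1229619, with 1229598 in K700E and 1229594 in wild type, and 19454837 to 19454872, with 19454855 and 19454848.

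Single pairs of tables differed more often and in the same direction. The top-ranked branch point differed between genotypes in 15.4% of the 50765 clusters in SF3A2 and in 20.4% in Flag, and between immunoprecipitations in 11.9% within K700E and 15.4% within wild type. Shifts went toward the nearer end in K700E in 61.5% of differing clusters in SF3A2 (60.4 to 62.5%) and 59.8% in Flag (58.9 to 60.8%). Between immunoprecipitations the share was 49.2% within K700E (47.9 to 50.4%) and 51.2% within wild type (50.1 to 52.3%). The top-ranked branch point lay within 9 nt of the nearer end in 11.3% and 11.6% of clusters in the SF3A2 and Flag K700E tables. In the SF3A2 and Flag wild-type tables it did so in 9.64% and 9.37%.

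The K700E tables also listed more branch points per cluster. Over all clusters of each table, the mean was 2.18 for K700E and 1.87 for wild type in SF3A2, a difference of 0.315 (0.307 to 0.323, normal interval over clusters). In Flag the means were 1.82 and 1.80, a difference of 0.0224 (0.0134 to 0.0315). In the 55666 clusters of all 4 tables, the mean was 2.72 for K700E and 2.17 for wild type in SF3A2, a difference of 0.551 (0.544 to 0.558), as an alternative chosen after seeing the data. In Flag the means of these clusters were 2.01 and 1.95, a difference of 0.0536 (0.0468 to 0.0603). Flag K700E listed more branch points than Flag wild type in 12852 of these clusters and fewer in 10563. Within these clusters 10283 branch points were listed in both K700E tables and neither wild-type table, and 4393 the reverse. Where both wild-type tables had the same top-ranked branch point, 56.7% of the K700E-specific branch points lay on its nearer-end side (55.7 to 57.8%). For wild-type-specific branch points, set against the top-ranked branch point of both K700E tables, 1410 lay on its nearer-end side and 2205 on the other (37.4 to 40.6% nearer). The other arrangements gave shares of 54.7% (53.1 to 56.4%) and 46.1% (43.2 to 49.1%) when crossed, and 49.8% for SF3A2-specific and 55.1% (51.9 to 58.2%) for Flag-specific branch points. The K700E share of 56.7% was above all 4 of these values, but its interval overlapped those of 54.7% and 55.1%. The wild-type share lay below all 4, with an interval that overlapped none of them. In both immunoprecipitations the K700E table was also the larger one. Over the 4 tables, the mean number of branch points per cluster ranked in the same order as table size. Table size therefore cannot be separated from genotype in the SF3A2 or the Flag difference in branch points per cluster.

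The immunoprecipitations were also compared with each other. Of the clusters seen only with SF3A2, those of 2 listing classes lay more often on 1 side of clusters of all 4 tables, and those of the most numerous class did not. Offsets were measured between mean top-ranked branch points, to the nearest cluster of all 4 tables with the same orientation. Among the 10569 clusters of both SF3A2 tables and neither Flag table, 1230 lay 40 to 200 nt from that cluster on its nearer-end side. As far on the other side lay 400, which gave a nearer-end share of 75.5% (73.3 to 77.5%). Among the 4736 clusters of the SF3A2 wild-type table alone the numbers were 1068 and 269, or 79.9% (77.6 to 81.9%). In these classes 11.7% and 22.7% of the oriented clusters lay in that nearer-end zone. The 22937 clusters of the SF3A2 K700E table alone gave 684 and 671, or 50.5% (47.8 to 53.1%). The 7217 clusters of both K700E tables only gave 129 and 148, or 46.6% (40.8 to 52.5%). The 460 clusters of both wild-type tables only, which are in a Flag table, gave 33 and 9, or 78.6% (64.1 to 88.3%). The one-sided offset was thus not limited to clusters seen only with SF3A2. Clusters of all but the Flag K700E table gave 59.9% (55.2 to 64.4%), and those of all but Flag wild type 54.7% (49.4 to 59.8%). Those of all but SF3A2 K700E gave 2 and 3. No class absent from the SF3A2 wild-type table exceeded 50.5%. High shares thus occurred only in classes listed there, though not in all of them. The 3′ splice site mark was present on 41.4% of the clusters of both SF3A2 tables only and 11.7% of those of the SF3A2 wild-type table alone. Offsets were examined after the classes had been seen.

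**Figure D5:**
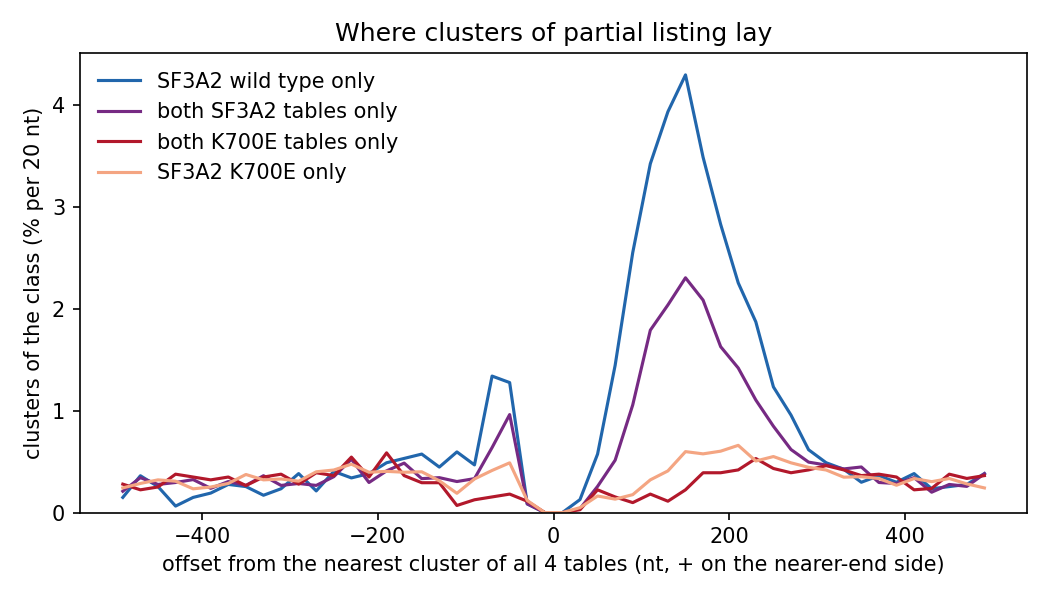
Percentage of the clusters of a class per 20 nt (y axis) by their offset in nt from the nearest cluster of all 4 tables with the same orientation (x axis, positive on its nearer-end side), to 500 nt on each side; lines are the 4 listing classes. Clusters of the SF3A2 wild-type table alone and of both SF3A2 tables only peak on the nearer-end side, where 79.9% and 75.5% of those 40 to 200 nt away lay.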

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

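The share of branch points in 3′ splice site clusters moved in opposite directions with genotype in the immunoprecipitations. In SF3A2 it was 64.9% for K700E and 64.1% for wild type, a difference of 0.838 percentage points (0.539 to 1.14). In Flag it was 68.3% and 69.3%, a difference of -1.04 percentage points (-1.40 to -0.688). These results stood out because the single pooled SF3A2 comparison and the single Flag comparison had opposite signs, and the difference between them was not tested. Counting each cluster once gave -0.104 in SF3A2, with an interval that included 0, and -1.03 in Flag.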

How the results depend on the processing

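Overlaps within 5 nt and by cluster were chosen before the data were examined, and the other alternatives after seeing them. Of 41 alternatives over 14 results, 15 stayed within the main interval or 1.5 times the main count, 25 moved beyond it without changing direction, and 1 reversed. The share of wild-type branch points also listed for K700E moved in SF3A2 from 81.4% to 93.1% within 5 nt, 93.6% by cluster, 78.2% with ranks 1 and 2, 73.4% with rank 1 and 86.3% in clusters of all 4 tables. In Flag it moved from 68.8% to 85.3%, 84.2%, 67.3%, 64.1% and 77.0%. The K700E minus wild-type difference in 3′ splice site branch points in SF3A2 was 0.440 percentage points with ranks 1 and 2 and reversed to -0.104 with each cluster counted once, and the cause was not tested. The difference in branch points per cluster in SF3A2 was 0.315 over all clusters, 0.147 with ranks 1 and 2 and 0.551 in clusters of all 4 tables. In Flag these were 0.0224, 0.0116 and 0.0536. The listing odds ratio of 5.64 rose to 9.65 in 3′ splice site clusters and 15.2 in clusters of 30 to 38 nt, and was 4.81 without the mark and 4.87 without windows that stood apart. Switched clusters were 4.85% at 30 to 38 nt and 3.63% with shifts of at least 3 nt. The share toward the nearer end, 72.0%, became 76.8% at 30 to 38 nt, 67.9% with at least 3 nt, 69.1% and 77.3% when oriented by the Flag wild-type or Flag K700E table, and 68.4% by neighbouring clusters. The correlation of window shares fell from 0.648 to 0.518 with windows of 5 Mb. The planned stricter signal thresholds, equal numbers of strongest sites, weights by signal, and alternatives for tests on counts, sequence, U12-type sites or distances were not run, because the tables hold no signal or sequence. No paired analysis was possible because the SF3A2 tables pool their replicates and each Flag group had 1 library. Depth is unknown, so a cluster missing from a table is not shown to be unbound.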

Other observations

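Some clusters found in both wild-type tables and neither K700E table lay close together. Of opposite-orientation neighbours within 20 kb of such a cluster, 1.19% (8 of 675) were of the same class. Neighbours were counted from each cluster of the class, so a pair of such clusters was counted from both sides. Of same-orientation neighbours, 5.32% (212 of 3983) were, against 0.375% of all clusters. A few loci supplied much of this: without the 4 intervals of 100 kb that held 5 or more such clusters, 24 of the 460 in all, the share was 2.42% (90 of 3723), an alternative chosen after seeing the data. For clusters found in both K700E tables only, 10.4% of same-orientation and 7.44% of opposite-orientation neighbours were of the class, against 5.88% of all clusters. The difference between the genotypes was not tested.

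The tests below were chosen after the result was seen, except those on neighbour orientation of switches, on neighbours of K700E-specific clusters and on the 1 Mb bins of chromosome X, which were fixed beforehand. In K700E the top-ranked branch point lay closer to the nearer cluster end in 72.0% of switches. Disagreement between tables of any kind would give as many switches in other arrangements, but the highest of them gave 660 against 2615. If only the larger SF3A2 K700E table gave the direction, the Flag tables would show none, and there 59.8% of differing clusters went toward the nearer end. The Flag K700E table was also the larger of its pair, with 134081 against 124989 branch points, so this does not exclude table size. The larger SF3A2 tables, set against Flag, gave 49.2% toward the nearer end within K700E and 51.2% within wild type. Size alone therefore gave little direction in those pairs. Orientation read from the same branch points would bring the share to about 50% when neighbours set the orientation, and it was 68.4% (66.6 to 70.2%). A change of branch point choice with K700E may therefore be the source, as a hypothesis. The genotypes came from different engineered cells, so a difference between lines remains open and untested.

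Genotype-specific clusters gathered in regions. With clusters shuffled over windows the highest rho of 100 shuffles was 0.254, against 0.648 observed. This argues against unequal listing by chance only if clusters are independent. Neighbouring clusters are not, so the shuffles did not test chance differences between whole genes or loci. Transcript levels of single genes may contribute. Neighbours within 20 kb of a cluster found only in both K700E tables were of that class more often with the same orientation than with the opposite one. The ratio was 1.40 (1.28 to 1.52, from 1000 resamples of clusters, as are the next intervals). For clusters found only in both wild-type tables it was 4.49 (2.46 to 11.7), with 8 opposite-orientation neighbours of the class. A pair with both clusters in the class was counted from each of them. The resamples treated these counts as independent, so the intervals may be too narrow. At 100 kb to 1 Mb the K700E ratio was still 1.10 (1.04 to 1.16), so not all of the 1.40 need come from single genes. The wild-type ratio there was 1.87 (0.928 to 4.73). At most 20 clusters on each side were searched, so regions with many clusters count less at this distance. A dosage change over chromosome X from 10 to 30 Mb stays open: 0 of 11 bins of 1 Mb lay at or below the genome-wide Flag share. Clusters of either orientation also lay above it. Their Flag shares were 87.4% (79.2 to 92.6%) with branch points nearer the end and 98.9% (94.2 to 99.8%) nearer the start. The region was picked for its high shares, so these values decide nothing, and copy number was not measured here.

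Branch points lay nearer 1 end of the cluster, and the strand is not in the tables. Clusters of opposite orientation may come from opposite strands: 92.7% of clusters shared the orientation of the next cluster 500 to 5000 nt on, against 49.3% at 1 to 3 Mb. Whether the nearer end is the 3′ end stays open. In runs of at least 5 marked clusters the gap at the nearer-end side was the shorter in 58.3% of 4862 runs (56.9 to 59.6%), but the test relied on long first introns, which gaps between 3′ splice site clusters do not measure, so it decides nothing. Strand was not tested directly, and a shift toward the nearer end is not shown to be a shift toward the 3′ splice site.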
